A study of Mus musculus with 26 samples.

How the data were processed

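The data came from 26 Smart-Seq2 libraries of haematopoietic stem cells (HSCs) sorted from mouse bone marrow, per the labels: control n = 5, JAK2V617F n = 7, Ezh2 loss n = 7, and JAK2V617F with Ezh2 loss (double-mutant) n = 7. Groups were taken from the genotype label, which spells the mutation of the double mutant JAK2V17F and was read as JAK2V617F. Replicate numbers follow the order of deposition and pair nothing. Age, sex, strain, cells per library, sequencer and read length are not given in the sources used here, and no independent sample of other mice was analysed here.

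The authors deposited a single table of RPKM (reads per kilobase of gene, scaled to the library total), with 23416 genes and 1 column per library, and 0 columns were left unmapped. Per the submitters' processing notes, STAR 2.4.2a, SAMtools 0.1.19 and Subread 1.5.0 were used with mm10/GRCm38. Their settings, the annotation, the gene lengths and the read total used are not given in the sources used here. Reads were not aligned again, and exons, junctions and the JAK2V617F base change were not analysed here.

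Depth was estimated from the RPKM values themselves. Low values of a gene lie on whole-number steps, 1 step per read, and the ratio of those steps between libraries gives their relative depth. The ratios were coherent in 313 of 325 library pairs, and 955 genes had whole steps in every library within a tolerance of 0.01. Exon lengths from GENCODE M21 then gave the total, on which 117 genes fell, against 13 at the next most common total. The estimates ran from 7.8 to 29.2 M reads (M for 10 to the power of 6), with means of 17.5 (control), 13.4 (JAK2V617F), 14.0 (Ezh2 loss) and 21.1 M (double-mutant). Genes at RPKM of at least 1 numbered 9223 to 11007 per library. Correlations between libraries ran from 0.762 to 0.91, and the number of equal non-zero values in any pair was 0. Of the symbols, 21751 were found in GENCODE M21, the source of all GRCm38 coordinates.

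Genes with RPKM of at least 1 in at least 5 libraries, the size of the smallest group, were tested: 12116 of 23416. limma 3.58.1 in R 4.3.3 was fitted to log2(RPKM + 1) with 1 mean per group and moderated variances (eBayes with trend and robust; median prior degrees of freedom 7.3). Each of the 6 contrasts was two-sided and adjusted by Benjamini-Hochberg, and a gene passed at adjusted p under 0.05: each mutant group against control, the double mutant against each single mutant, and the interaction, which is the double mutant minus both single mutants plus control. Fold changes are log2 with the standard error (SE) of the limma fit, and levels are mean RPKM ± SD over libraries. Wherever an adjusted p is given for a gene it is that of limma unless another test is named. A fold change of 0 on the log2 scale means equal RPKM, and values near 0 RPKM are compressed by the added 1.

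The 28 gene lists were fixed before the data were examined, and 24 had at least 5 tested genes. They were tested with camera (limma) at a preset correlation of 0.01 between genes, two-sided, adjusted over 144 tests of 24 lists in 6 contrasts. An estimated correlation and fry, a rotation test, were alternatives. The camera test ranks a list against all other genes, so a list can pass upward while few of its genes pass. Beside each list stands the number of members that pass when p-values are adjusted over the list alone. Median fold changes of the tested genes differed from 0 in several contrasts, and camera is not moved by such a shift. The B cell (3), T and NK cell (4), mast cell and basophil (2) and mitochondrially encoded (0) lists had too few tested genes.

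Ezh2 and Jak2 are always named. In each contrast the named genes are the 10 largest rises and 10 largest falls with adjusted p under 0.05 and a mean RPKM of at least 5 in the higher group, passing over predicted genes and pseudogenes, plus list members with adjusted p under 0.05, at most 4 per list by smallest adjusted p. A list that passes has 2 to 4 members named by smallest p even where none passes. Where fewer than 5 genes pass, the 5 genes with the smallest p are named as not passing. Any other gene is said to be chosen after its values were seen. Some genes that meet this rule are not reported here.

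The grouping, the main test, the lists, the naming rule and the alternatives for pseudocount (0.1 and 5), low-value filter, scaling (median ratio in place of TMM, quantile, TPM), libraries in the fit, array weights, library naming style, detected genes, Xist, fold threshold and leaving out each of the 26 libraries were set before the data were examined. After the data were seen came the neutrophil covariate (mean log2 of Camp, Ngp, Ltf, Lcn2, Mmp8 and Retnlg), the joint covariate of naming style and neutrophils, the list tests in number-first libraries, the similarity of effects with the style covariate, the splits within naming style, the additive fit of naming style, JAK2V617F and Ezh2 loss without an interaction, and exact permutation tests of 5 genes. The genes of these last tests were chosen for the values tested, so their p-values are not used. A test for read counts was not run, because the table holds RPKM.

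Naming style refers to the library titles, which have a running number before the group code (number-first) or after it (number-last). Its meaning is not given in the sources used here. The number-first and number-last libraries were 4 and 1 of control, 2 and 5 of JAK2V617F, 2 and 5 of Ezh2 loss, and 7 and 0 of the double mutant.

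The tests were tried on simulated data of 12116 genes with 200 changed genes. For the double mutant against JAK2V617F, without a style difference, limma recovered 18.4%, 57.6% and 76.2% of true changes of log2 1, 2 and 3, with 8.2 false calls on average. With a simulated style difference like that of the data, false calls rose to 208.2 on average (162.3 against Ezh2 loss, 3.6 against control). The style covariate brought them to 3.6, 4.1 and 4.3, and recovery in the first of these contrasts was then 9.4%, 43% and 71.1%. Lists were tried in 20 runs without a style difference, with the type I interferon list raised by log2 1 in the double mutant. For the double mutant against control, camera called that list in 20 runs at the preset correlation and in 18 with an estimated one. At the preset correlation it also called 2.15 unchanged lists per run on average, so its list calls can be false. For chance, group labels were exchanged between the libraries compared in 100 splits that keep group sizes (36 where fewer exist within a naming style). The seed of the splits was 7. Near-identical copies were searched with blastn 2.17.0. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made tables and figures.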

Results

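HSCs, the cells that renew themselves and feed every blood lineage, were compared between control mice (n = 5 libraries), mice with the myeloproliferative driver JAK2V617F (n = 7), mice with loss of Ezh2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (n = 7), and double-mutant mice (n = 7). Levels are RPKM and fold changes are log2. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples.

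Ezh2 RNA was at 23.7 ± 10.4 in control, 27.1 ± 8.21 in JAK2V617F, 17.6 ± 9.0 in Ezh2 loss and 17.4 ± 9.07 in double-mutant HSCs. The fold changes did not pass: -0.43 for Ezh2 loss against control (SE 0.41, adjusted p = 0.792) and -0.43 for the double mutant against control (SE 0.41, adjusted p = 0.986). Against JAK2V617F the double mutant was at -0.72 (SE 0.38, adjusted p = 0.316). In number-first libraries alone the direction for Ezh2 loss against control turned (0.08 in log2, with means of 21.2 and 21.3 RPKM). By library, in replicate order, Ezh2 was at 18.1, 29.6, 29.5, 8.11 and 33.2 in control. It was at 24.9, 37.5, 24.0, 20.4, 20.7, 40.2 and 21.9 in JAK2V617F. The Ezh2 loss libraries had 5.15, 16.4, 14.8, 27.6, 15.4, 31.4 and 12.6, and the double-mutant libraries 28.3, 13.2, 31.4, 15.1, 11.1, 6.71 and 15.8. The labels used here do not say which part of Ezh2 is removed, and the gene-level value sums all exons, so a transcript that lacks an exon is still counted.

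Jak2 RNA was at 16.2 ± 4.71 in control, 12.8 ± 5.71 in JAK2V617F, 17.8 ± 9.37 in Ezh2 loss and 11.3 ± 7.93 in double-mutant HSCs. No change passed: -0.51 for JAK2V617F against control (SE 0.55, adjusted p = 0.82), -0.76 for the double mutant against control (SE 0.55, adjusted p = 0.977) and -0.77 for the double mutant against Ezh2 loss (SE 0.50, adjusted p = 0.476). By library, Jak2 was at 17.1, 19.3, 14.1, 21.2 and 9.17 in control and at 11.4, 14.8, 18.9, 14.5, 0.996, 13.2 and 15.8 in JAK2V617F. It was at 11, 11, 13.5, 30.3, 25.6, 6.65 and 26.5 in Ezh2 loss and at 11.6, 23.5, 14.1, 4.44, 18.2, 5.82 and 1.57 in the double mutant. The V617F base change cannot be read from gene-level RPKM.

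The largest difference between these libraries followed their naming style and not their genotype. The first principal component (16.3% of the variance, against 7% for the second) placed number-first libraries at 13 to 59 and number-last libraries at -69.7 to -24.8. In the additive fit, added after the data were seen, 2327 of 12116 genes (19.2%) differed by naming style, 1700 higher and 627 lower in number-first libraries. Ribosomal protein genes led the rises, with 53 of 81 called: Rpl13 (fold change 4.34; 1880 against 93.2), Rpl5 (5.17) and Rpl23a (6.86). Ppia (6.67; 1630 against 15.7) and Gapdh (3.89; 264 against 17.1) were also higher, while Gm15421 (-5.97; 1.47 against 157) and Mir682 (-5.18; 25.5 against 943) were lower. Many of these genes have near-identical copies in the genome, so their own level is uncertain.

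**Figure D1:**
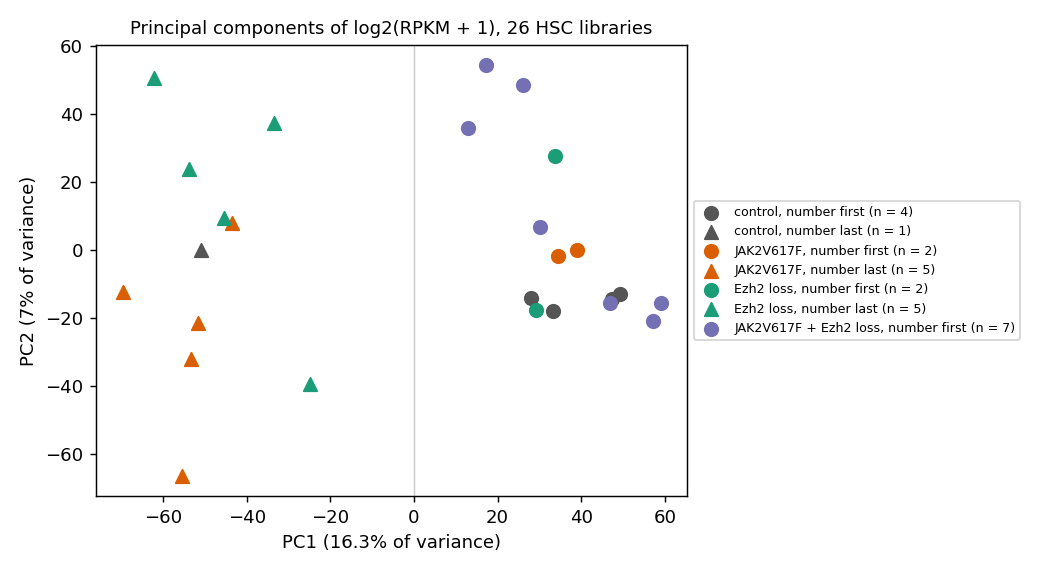
Principal components of log2(RPKM + 1) for the 26 libraries, with genotype as colour and naming style as symbol. The first component (16.3%) parts the naming styles.

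Genotype and naming style overlapped: 4 of 5 control and 7 of 7 double-mutant libraries were number-first, against 2 of 7 JAK2V617F and 2 of 7 Ezh2 loss libraries. Each single mutant against control, the double mutant against either single mutant, and the interaction are therefore mixed with naming style. The double mutant against control is nearly free of it. Gene counts and list tests of the 6 contrasts are given without the style term, with it as a covariate and in the number-first libraries alone, the last of which was added for the lists after the data were seen.

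In JAK2V617F against control HSCs, the dynein light chain gene Dynlt1b fell from 13.3 ± 9.6 to 0.0631 ± 0.138 RPKM (-3.22, SE 0.54, adjusted p = 0.0229). It has near-identical neighbours, so the call is uncertain, and no other gene passed. The phosphodiesterase gene Pde2a (-2.39, SE 0.45, adjusted p = 0.057, from 9.13 to 0.814 RPKM) and the AP-1 gene Jun (-1.83, SE 0.38, adjusted p = 0.136, from 103.7 to 29.0 RPKM) did not pass. Nor did Csrp1 (-2.63, SE 0.56, adjusted p = 0.166) and Mrps30 (-1.22, SE 0.27, adjusted p = 0.25). With the style covariate Dynlt1b was at -2.86 (SE 0.58, adjusted p = 0.386). Within number-first libraries it was at 14.2 in control (n = 4) and 0.221 in JAK2V617F (n = 2), and within number-last libraries at 9.81 (n = 1) and 0 (n = 5). The limma count was 1 (0 up, 1 down; 961 at unadjusted p under 0.05), 0 with the style covariate (501) and 0 in number-first libraries (334). The call was lost, leaving 0 genes, without control replicate 2 or 4 or JAK2V617F replicate 2, 4, 5 or 7. By contrast 3 genes passed without control replicate 5 or JAK2V617F replicate 1 or 3, and 2 without JAK2V617F replicate 6. The median gene moved by -0.113, so small falls are near the general shift.

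Immediate early and stress genes ranked lower in JAK2V617F HSCs (21 of 24 lower, adjusted p = 0.0214, adjusted p = 0.762 with an estimated correlation, 0.00315 with the style covariate and 0.000106 in number-first libraries). No member passed over all genes, and 3 passed over the list alone: Jun, Junb (-1.78, SE 0.54) and Ier2 (-0.88, SE 0.28). JAK-STAT target genes, which JAK2V617F would be thought to raise, also ranked lower (18 of 21 lower, adjusted p = 0.0257, adjusted p = 0.599 with an estimated correlation, 0.393 with the style covariate and 0.68 in number-first libraries). Over all genes 0 passed, and 2 over the list alone (Gfi1b -0.71, Junb). MHC class II genes such as H2-Eb1 (2.02) and H2-Ab1 (1.61) ranked higher (8 of 9, median 0.52, adjusted p = 0.000271, adjusted p = 0.409 with an estimated correlation, 0.000101 with the style covariate and 0.416 in number-first libraries). None passed over all genes, and 0 over the list alone. Cell cycle genes such as Tpx2 (1.94) and Mcm6 (0.67) ranked higher (32 of 44, adjusted p = 0.000321, adjusted p = 0.762 with an estimated correlation, 0.0712 with the style covariate and 0.000249 in number-first libraries). So did nuclear oxidative phosphorylation genes such as Uqcrfs1 (0.54) and Sdhb (0.61) (23 of 36, adjusted p = 0.0498, adjusted p = 0.777 with an estimated correlation, 0.0312 with the style covariate and 0.00263 in number-first libraries). Inflammation genes such as S100a4 (1.02) and Anxa1 (0.54) ranked higher as well (14 of 21, adjusted p = 0.0374, adjusted p = 0.607 with an estimated correlation, 0.179 with the style covariate and 0.0982 in number-first libraries). In each of these 3 lists 0 members passed over the list alone. Ribosomal protein genes ranked lower (55 of 81 lower, adjusted p = 0.00547, adjusted p = 0.826 with an estimated correlation), but higher with the style covariate (0.000101) and in number-first libraries (2.64e-05), so no direction is given for them.

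In Ezh2 loss against control HSCs, transcripts of neutrophils appeared. Retnlg went from 0 in every control library to 142 ± 182 RPKM (5.99, SE 1.21, adjusted p = 0.245). S100a8 went from 80.1 to 10610 (6.47, SE 1.77), S100a9 moved by 6.10 (SE 1.78) and Ngp went from 2.05 to 1159 (6.27, SE 2.3). With all groups in the limma fit none of these passed, and their spread between libraries was large. With only the groups compared Retnlg passed (5.99, SE 0.79, adjusted p = 0.0081). S100a8 lay above the highest control (203) in 7 of 7 Ezh2 loss libraries. By naming style its means were 93.4 and 4597 in number-first control (n = 4) and Ezh2 loss (n = 2), and 26.6 and 13020 in number-last control (n = 1) and Ezh2 loss (n = 5). The haemoglobin gene Beta-s was higher too, without passing (4.95, SE 1.15, adjusted p = 0.269). The difference was far larger in number-last libraries, from 10.8 to 2339 RPKM, than in number-first libraries, from 12.6 to 28.0, and 7 of 7 Ezh2 loss libraries lay above the highest control (16.8).

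**Figure D2:**
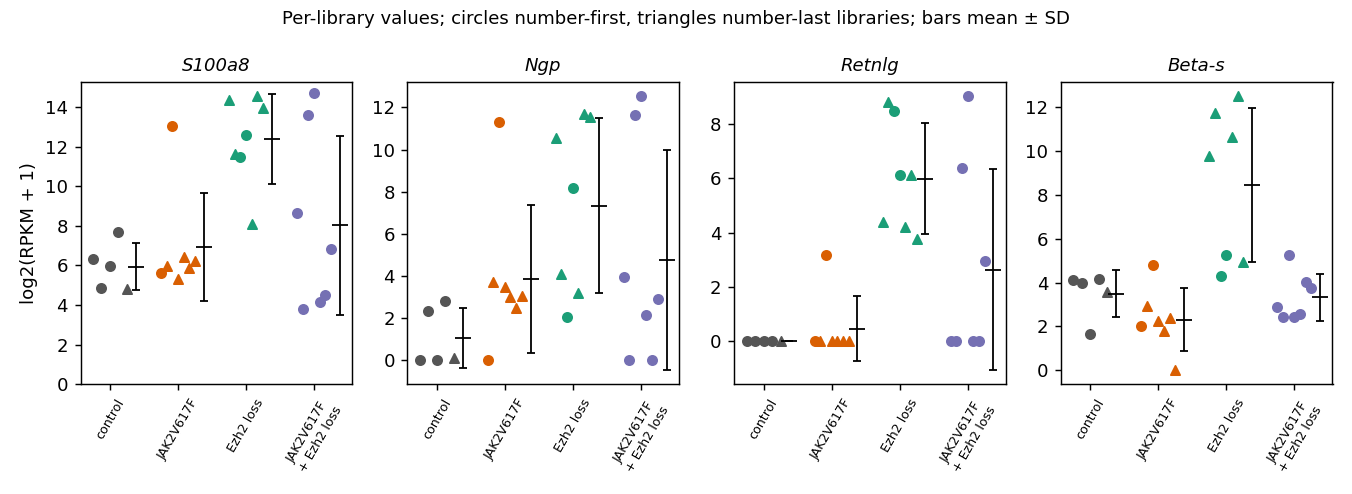
S100a8, Ngp, Retnlg and Beta-s per library as log2(RPKM + 1) in the 4 groups, circles for number-first and triangles for number-last libraries, bars for mean ± SD. S100a8 lay above the highest control in 7 of 7 Ezh2 loss libraries and 3 of 7 double-mutant libraries.

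The other genes with the smallest p for Ezh2 loss against control were Noxa1 (-2.95, SE 0.62) and the JAK-STAT feedback gene Socs2 (-2.0, SE 0.44, from 41.1 to 10.7 RPKM). Xbp1 (-0.84, SE 0.18) and Aldh1l1 (2.34, SE 0.53) followed, all with adjusted p = 0.245. The limma count was 0 (1008 at unadjusted p under 0.05), 0 with the style covariate (736) and 0 in number-first libraries (806), and it was 1 only without double-mutant replicate 4. The median gene moved by -0.116.

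Among the lists, granulocyte and monocyte genes ranked higher after Ezh2 loss (19 of 22, adjusted p = 6.82e-07, adjusted p = 0.494 with an estimated correlation, 1.39e-10 with the style covariate and 2.64e-05 in number-first libraries). They were led by Camp (6.96), with 0 passing over all genes and 1, Retnlg, over the list alone. Inflammation genes ranked higher (16 of 21, adjusted p = 6.13e-05, adjusted p = 0.329 with an estimated correlation, 0.00116 with the style covariate and 0.0158 in number-first libraries). Over the list alone 5 passed: S100a8, S100a9, Lgals3 (3.12), Ptgs2 (1.56) and Lcn2 (5.22). Erythroid genes ranked higher (10 of 12, adjusted p = 0.000211, adjusted p = 0.521 with an estimated correlation, 0.0173 with the style covariate and 0.716, downward, in number-first libraries), with 3 passing over the list alone, among them Alas2 (2.35) and Rhd (2.58). Type I interferon genes such as Gbp2 (0.85) and Ifi27l2a (3.49) ranked higher (20 of 28, adjusted p = 0.000271, adjusted p = 0.521 with an estimated correlation, 0.00116 with the style covariate and 0.0158 in number-first libraries). MHC class II genes such as H2-Eb1 (1.73) and H2-Ob (0.90) did too (9 of 9, adjusted p = 0.0352, adjusted p = 0.629 with an estimated correlation, 0.0461 with the style covariate and 0.527 in number-first libraries), and so did cell cycle genes such as Kif11 (2.17) and Plk1 (2.69) (35 of 44, adjusted p = 6.82e-07, adjusted p = 0.637 with an estimated correlation, 0.000943 with the style covariate and 2.42e-05 in number-first libraries). In these 3 lists 0 members passed over the list alone. Lymphoid priming genes ranked higher (6 of 9, adjusted p = 0.0257, adjusted p = 0.341 with an estimated correlation, 0.0867 with the style covariate and 0.281 in number-first libraries), with 2 passing over the list alone (Cd52 4.80, Cd53 2.41).

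Genes of the HSC state ranked lower after Ezh2 loss (24 of 33 lower, adjusted p = 0.0245, adjusted p = 0.644 with an estimated correlation, 0.266 with the style covariate and 0.399 in number-first libraries). Tcf15 (-3.42), Mycn (-1.09) and Erg (-1.62) were the 3 that passed over the list alone. Tcf15 was at 17.5 RPKM in the only number-last control against 73.6 to 85.7 in the other controls, so its fall is mixed with naming style. JAK-STAT target genes ranked lower (19 of 21 lower, adjusted p = 0.00901, adjusted p = 0.537 with an estimated correlation, 0.277 with the style covariate and 0.68 in number-first libraries). Over the list alone 4 passed downward (Socs2, Cish -1.52, Pim2 -1.82, Ccnd1) and 2 upward (Lrg1 2.78, Bcl6 1.77). MYC and ribosome biogenesis genes such as Mycn and Myc (-0.74) ranked lower (18 of 24 lower, 1 over the list alone, adjusted p = 0.0426, adjusted p = 0.607 with an estimated correlation, 0.0446 with the style covariate and 0.155 in number-first libraries). Glycolysis genes such as Pkm (-0.80) and Gapdh (-2.02) ranked lower (15 of 18 lower, 1 over the list alone, adjusted p = 0.0373, adjusted p = 0.607 with an estimated correlation, 0.179 with the style covariate and 0.291 in number-first libraries). Gapdh differed strongly by naming style (264 RPKM in number-first against 17.1 in number-last libraries), so its fall here cannot be told from style. Ribosomal protein genes ranked lower (62 of 81 lower, adjusted p = 1.81e-05, adjusted p = 0.762 with an estimated correlation), but higher with the style covariate (0.0847) and in number-first libraries (0.0313), so no direction is given for them.

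In double-mutant against control HSCs, 9 of 9 lymphoid priming genes were higher, with a median fold change of 1.05, led by Flt3 (2.01, SE 0.64), Cd52 (3.28, SE 1.56) and Cd53 (1.80, SE 0.89). This was the only list of the 6 contrasts that passed with the preset correlation (adjusted p = 0.000271) and with an estimated correlation (0.0327). Its estimated correlation was -0.02, under the preset 0.01, so for this list the second test allowed for no more correlation than the first, while other lists had up to 0.451. It also passed with the style covariate (0.000261, and 0.0317 with an estimated correlation) and in number-first libraries (0.00127). Among its members 0 passed over all genes and 1, Flt3, over the list alone. Flt3, a receptor of early lymphoid and myeloid progenitors, is low in the most primitive HSCs. Neutrophil transcripts were present in the same group, with S100a8, Lcn2 and Retnlg above the highest control in 3 of 7 libraries. Cd52 and Cd53 are found on many leukocytes, so a source in other cells was not excluded for them.

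Type I interferon genes were higher in double-mutant than control HSCs (22 of 28, adjusted p = 2.1e-05, adjusted p = 0.409 with an estimated correlation, 7.38e-06 with the style covariate and 2.02e-06 in number-first libraries). Over all genes 0 passed, and 6 over the list alone, among them Gbp2 (1.21), Ifi27l2a (4.64), Ifit1 (1.64), Oasl2 (0.92) and Ifit3 (2.56). MHC class II genes such as H2-Ob (2.05) and Cd74 (1.43) ranked higher (9 of 9, 0 over the list alone, adjusted p = 0.000919, adjusted p = 0.494 with an estimated correlation, 0.00152 with the style covariate and 0.03 in number-first libraries). Inflammation genes ranked higher (17 of 21, with Lgals3 3.38 the 1 member passing over the list alone and S100a9 at 3.28, adjusted p = 0.0245, adjusted p = 0.598 with an estimated correlation, 0.0197 with the style covariate and 0.0215 in number-first libraries). Granulocyte and monocyte genes such as Csf3r (1.25) and Csf1r (1.26) ranked higher (19 of 22, 0 over the list alone, adjusted p = 7.29e-05, adjusted p = 0.596 with an estimated correlation, 0.00152 with the style covariate and 0.00557 in number-first libraries). Immediate early and stress genes such as Hsp90aa1 (-0.52) and Ppp1r15a (-0.70) ranked lower (21 of 24 lower, 0 over the list alone, adjusted p = 0.000271, adjusted p = 0.607 with an estimated correlation, 0.000261 with the style covariate and 0.00053 in number-first libraries). Quiescence genes ranked lower (13 of 18 lower, with Fhl1 -1.22 the 1 member passing over the list alone and Rb1 at -1.23, adjusted p = 0.0352, adjusted p = 0.607 with an estimated correlation, 0.0806 with the style covariate and 0.0928 in number-first libraries).

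No single gene passed in double-mutant against control HSCs. The smallest p belonged to Cyb5 (-0.62, SE 0.14, adjusted p = 0.566), Ost4 (-0.61, SE 0.14, adjusted p = 0.566) and the peptide-loading gene Tapbp (0.84, SE 0.19, adjusted p = 0.566). Tacc1 (1.37, SE 0.32, adjusted p = 0.61) and Mir3470a (2.07, SE 0.52, adjusted p = 0.674) followed. The limma count was 0 (603 at unadjusted p under 0.05) in all 26 settings that leave out a library. It was 1 with the style covariate (748), the gene being Gm2a (1.55, SE 0.26, adjusted p = 0.0181), and 0 in number-first libraries (819). The median gene moved by 0.034.

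In double-mutant against JAK2V617F HSCs, 3 genes passed with and without the style covariate. Pde2a rose from 0.814 ± 0.974 to 22.6 ± 7.01 RPKM (3.81, SE 0.41, adjusted p = 3.25e-06, 3.17 and 0.0011 with the covariate). Dynlt1b, uncertain for its near-identical copies, rose from 0.0631 to 22.5 RPKM (4.43, SE 0.50, adjusted p = 4.76e-06, 3.92 and 0.0011 with the covariate). The oestrogen receptor gene Esr1 fell from 21.2 ± 8.59 to 0.265 ± 0.185 RPKM (-4.07, SE 0.49, adjusted p = 1.41e-05, -4.07 and 0.0011 with the covariate). Within number-first libraries (n = 2 JAK2V617F, n = 7 double-mutant) Esr1 was at 20.2 and 0.265, Pde2a at 1.80 and 22.6, and Dynlt1b at 0.221 and 22.5. Vwf, which marks HSCs primed for platelets, fell from 14.4 ± 5.71 to 3.77 ± 1.38 RPKM (-1.66, SE 0.38, adjusted p = 0.02). With the covariate it was at -1.78 (adjusted p = 0.173), and within number-first libraries it was at 14.8 and 3.77.

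Type I interferon genes were higher in double-mutant than JAK2V617F HSCs (26 of 28, adjusted p = 0.000919, adjusted p = 0.567 with an estimated correlation, 2.93e-05 with the style covariate and 0.00132 in number-first libraries). Irf7 (2.21, SE 0.43, adjusted p = 0.0133, from 14 to 64.4 RPKM) and Oasl2 (1.21, SE 0.29, adjusted p = 0.0271) passed over all genes. Over the list alone 6 passed, among them Irf9 (0.78), Rsad2 (1.79) and Ifi27l2a (3.52). Lymphoid priming genes were higher (9 of 9, adjusted p = 0.0257, adjusted p = 0.341 with an estimated correlation, 0.00315 with the style covariate and 0.00194 in number-first libraries). Of these 1, Gm4759 (2.80, SE 0.73, adjusted p = 0.0376), passed over all genes, and 2, Gm4759 and Flt3 (1.96), over the list alone. Gm4759 is an unprocessed pseudogene in GENCODE M21, so its call is uncertain, and it was at 1.43 with the style covariate (adjusted p = 0.68). Nuclear oxidative phosphorylation genes ranked lower (23 of 36 lower, adjusted p = 0.00398, adjusted p = 0.66 with an estimated correlation, 0.000661 with the style covariate and 0.000741 in number-first libraries). Over all genes 2 fell, Uqcrh (-0.71, SE 0.14, adjusted p = 0.0133) and Atp5e (-0.63, SE 0.16, adjusted p = 0.0313), against 1 up and 9 down over the list alone. Cell cycle genes such as Cdc6 (-1.45) and Tyms (-1.0) ranked lower (28 of 44 lower, 0 over the list alone, adjusted p = 0.0383, adjusted p = 0.839 with an estimated correlation, 0.886 with the style covariate and 0.468 in number-first libraries). Ribosomal protein genes did not pass (50 of 81 higher, adjusted p = 0.556), although Rps26 (-0.84, adjusted p = 0.00498), Rplp0 and Rps27l fell, and the list ranked lower with the style covariate (8.61e-25) and in number-first libraries (5.82e-19).

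Among other list members in this contrast, Jun (2.16, SE 0.34, adjusted p = 0.00196), the Polycomb partner Phf1 (2.34, adjusted p = 0.0185), the endothelial and HSC gene Eng (1.34, adjusted p = 0.0187) and Gfi1b (0.80, adjusted p = 0.0241) rose. By contrast Hsp90aa1 (-0.83, adjusted p = 0.0201), Ifitm1 (-0.78, adjusted p = 0.0201), the growth arrest gene Gadd45g (-1.28, adjusted p = 0.0256), Canx (-1.35, adjusted p = 0.0313) and Npm1 (-0.47, adjusted p = 0.043) fell. The other large rises were Tnfrsf14 (4.04, adjusted p = 0.0122), Cap1 (3.73, adjusted p = 0.0133), and Tbl1x (3.08, adjusted p = 0.02). Smaller rises were those of Ankrd54 (3.05, adjusted p = 0.018), Phactr2 (2.92, adjusted p = 0.0215), Mier2 (2.91, adjusted p = 0.0133), Elmod3 (2.83, adjusted p = 0.0273) and Bsdc1 (2.82, adjusted p = 0.0197). The other large falls were Lars2 (-2.99, adjusted p = 0.0256), Fam102b (-2.34, adjusted p = 0.0273), the dendritic cell receptor gene Clec9a (-2.11, adjusted p = 0.0232), and Cd38 (-2.05, adjusted p = 0.0273). Those of the following genes are uncertain for near-identical copies: Mir682 (-4.28), Rn45s (-3.51), Uchl4 (-2.84), Hist1h4i (-2.75) and Stxbp3b (-2.71). None of the genes in these sentences passed with the style covariate.

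The limma count for the double mutant against JAK2V617F was 274 (168 up, 106 down), 4 with the style covariate (2 up, 2 down) and 0 in number-first libraries alone (760 at unadjusted p under 0.05). The remaining gene of the 4 was Rpl39 (-1.09, SE 0.21, adjusted p = 0.0408), a ribosomal protein gene with copies. All 274 kept their sign with the covariate, and the median gene moved by 0.142. The count was 172, 121, 148, 124, 159 and 156 without double-mutant replicates 1, 2, 4, 5, 6 and 7. It was 602, 131, 673, 168, 115, 83 and 116 without JAK2V617F replicates 1 to 7. The rises to 602 and 673 came from removing its number-first libraries.

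In double-mutant against Ezh2 loss HSCs, none of the calls passed with the style covariate. The haemoglobin gene Beta-s fell from 1679 ± 2180 to 12.2 ± 12.0 RPKM (-5.12, SE 1.05, adjusted p = 0.0355). Number-last Ezh2 loss libraries were at 2339 (n = 5) and number-first ones at 28.0 (n = 2), so most of this fall came from the number-last libraries. The HSC transcription factor Erg rose from 5.58 ± 4.43 to 25.3 ± 10.8 RPKM (2.25, SE 0.47, adjusted p = 0.0355, and 1.84 with the covariate). Eng (1.22, SE 0.30, adjusted p = 0.0478) and Mycn (1.21, SE 0.29, adjusted p = 0.0478) rose too, while the HSC list as a whole did not pass (adjusted p = 0.06). The chromatin remodelling gene Arid1a (-1.69, SE 0.33, adjusted p = 0.035) fell. S100a8 was lower by an amount that did not pass (-4.36).

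Erythroid genes ranked lower in the double mutant than in Ezh2 loss (12 of 12 lower, adjusted p = 0.000301, adjusted p = 0.537 with an estimated correlation, 0.0913 with the style covariate and 0.749, upward, in number-first libraries). Over all genes 0 passed, and 4 over the list alone, among them Klf1 (-2.78), Alas2 (-2.20) and Rhd (-2.50). Cell cycle genes such as Kif11 (-1.79) and Mki67 (-1.36) ranked lower (36 of 44 lower, 0 over the list alone, adjusted p = 0.000211, adjusted p = 0.762 with an estimated correlation, 0.179 with the style covariate and 0.0459 in number-first libraries). Immediate early and stress genes ranked lower (17 of 24 lower, with Hspa1a -1.93 and Klf4 -2.16 the 2 passing over the list alone, adjusted p = 0.0167, adjusted p = 0.762 with an estimated correlation, 0.0212 with the style covariate and 0.00557 in number-first libraries). Nuclear oxidative phosphorylation genes ranked lower (23 of 36 lower, adjusted p = 0.0179, adjusted p = 0.761 with an estimated correlation, 0.0161 with the style covariate and 0.0304 in number-first libraries). Uqcrh (-0.69, SE 0.14, adjusted p = 0.035) was the 1 member passing over all genes and over the list alone. JAK-STAT target genes such as Pim2 (2.04) and Socs2 (1.31) ranked higher (17 of 21 higher, 7 up and 1 down over the list alone, adjusted p = 0.0423, adjusted p = 0.607 with an estimated correlation, 0.854 with the style covariate and 0.984 in number-first libraries). Glycolysis genes ranked higher (14 of 18 higher, adjusted p = 0.0179, adjusted p = 0.598 with an estimated correlation, 0.0893 with the style covariate and 0.0982 in number-first libraries). Pkm (0.93, SE 0.21, adjusted p = 0.041) passed over all genes and 5 members over the list alone. Ribosomal protein genes ranked higher (53 of 81, adjusted p = 0.0352, adjusted p = 0.866 with an estimated correlation), but lower with the style covariate (6.97e-18) and in number-first libraries (1.03e-11), while Rplp0 (-0.65) and Rps27l (-0.57) were below 0 in both fits without passing.

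The other rises were Anxa11 (3.33, adjusted p = 0.0364), Nek6 (3.13, adjusted p = 0.0364), Asna1 (2.92, adjusted p = 0.0478) and Tbl1x (2.87, adjusted p = 0.0478). Phactr2 (2.79, adjusted p = 0.0478), Supt16 (2.77, adjusted p = 0.041) and Fam57a (2.61, adjusted p = 0.041) rose as well. So did Mier2 (2.57, adjusted p = 0.041), Prrg4 (2.56, adjusted p = 0.0468) and the adhesion gene Icam1 (2.51, adjusted p = 0.041, from 16.8 to 60.1 RPKM). The other falls were Lars2 (-3.40, adjusted p = 0.0355), Ptpn12 (-1.81, adjusted p = 0.032), and Snhg6 (-1.40, adjusted p = 0.0399). Cenpw (-1.38, adjusted p = 0.0468), Snord47 (-1.37, adjusted p = 0.041), Mir703 (-1.18, adjusted p = 0.032) and the repeated Rn45s (-3.65, adjusted p = 0.0413), which is uncertain, fell too.

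The limma count for the double mutant against Ezh2 loss was 85 (60 up, 25 down), 61 after median-ratio scaling (35 up, 26 down) and 0 with the style covariate (950 at unadjusted p under 0.05). With Xist, a gene expressed in females, as the covariate it was 0 as well (1664), with a smallest adjusted p of 0.062 and the same sign in 85 of 85. Mean Xist was 20.8 RPKM in Ezh2 loss and 4.62 in the double mutant. It also differed by naming style, with 22.1 in number-last and 6.86 in number-first libraries. The Xist covariate therefore cannot tell sex from style, and sex was not excluded here. In number-first libraries 8 genes passed, all upward (1120): Sertad3 (3.45), Tpm4 (3.27), Tha1 (3.09), Prkx (2.99), Gpr89 (2.77), Prmt2 (2.56), Lias (2.27) and Tspan14 (1.52), with adjusted p from 0.0298 to 0.0488. The median gene moved by 0.141. The count was 52, 49 and 51 without control replicates 1, 3 and 4, and 56 without JAK2V617F replicate 4. It was 29 without double-mutant replicate 1, and 0 without double-mutant replicate 2, 4, 5, 6 or 7. It was 1, 16, 173, 218, 11, 0 and 6 without Ezh2 loss replicates 1 to 7. The rises to 173 and 218 came from removing its number-first libraries.

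For the interaction, genes lay above or below the level that adding both single effects gives. Erg (3.28, SE 0.70, adjusted p = 0.0171), Tcf15 (5.05, SE 1.18, adjusted p = 0.0246), and Eng (1.89, adjusted p = 0.0246) passed upward, while the HSC list did not pass (23 of 33 higher, adjusted p = 0.176). So did Jun (2.50, SE 0.51, adjusted p = 0.0171), Junb (2.91, adjusted p = 0.0378), Irf7 (2.81, adjusted p = 0.0246), and Cish (2.19, adjusted p = 0.0422). Phf1 (3.06, adjusted p = 0.0318), Nkx2-3 (1.87, adjusted p = 0.0387), Pkm (1.35, adjusted p = 0.0249) and Gapdh (4.96, adjusted p = 0.0349) passed upward. Nkx2-3 is on the list of Polycomb-silenced genes but was expressed in control HSCs (46.6 RPKM). Its level was 28.55 in JAK2V617F, 30.0 in Ezh2 loss and 56.0 in the double mutant, so it was not higher in Ezh2 loss than in control. Esr1 (-3.15, SE 0.73, adjusted p = 0.0246) and Arid1a (-2.64, SE 0.49, adjusted p = 0.0171) passed downward. With the style covariate none passed. Esr1 was then at -3.15 (SE 0.94, adjusted p = 0.694), Erg at 2.58, Irf7 at 2.22 and Jun at 1.90 (each adjusted p = 0.753), Junb at 0.44 and Gapdh at 0.29. Tcf15 was then at 1.38 (adjusted p = 0.887).

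Of 7 lists that passed in the interaction, 2 also passed in the same direction with the style covariate, cell cycle and oxidative phosphorylation. JAK-STAT target genes ranked higher (17 of 21, adjusted p = 0.0111, adjusted p = 0.547 with an estimated correlation, 0.559 with the style covariate and 0.813 in number-first libraries). Junb and Cish passed over all genes, against 9 up and 1 down over the list alone. Glycolysis genes ranked higher, with Pkm and Gapdh passing over all genes and 3 over the list alone (15 of 18, adjusted p = 0.0213, adjusted p = 0.599 with an estimated correlation, 0.117 with the style covariate and 0.441 in number-first libraries). Cell cycle genes such as Kif11 (-3.03) and Tpx2 (-2.91) ranked lower (35 of 44 lower, 0 over the list alone, adjusted p = 1.17e-05, adjusted p = 0.694 with an estimated correlation, 0.0377 with the style covariate and 8.34e-05 in number-first libraries). Inflammation genes such as S100a8 (-5.36) and Il18 (-0.71) ranked lower (17 of 21 lower, 0 over the list alone, adjusted p = 0.0195, adjusted p = 0.596 with an estimated correlation, 0.175 with the style covariate and 0.139 in number-first libraries). Erythroid genes such as Rhd (-2.68) and Alas2 (-1.87) ranked lower (10 of 12 lower, 0 over the list alone, adjusted p = 0.0246, adjusted p = 0.694 with an estimated correlation, 0.69 with the style covariate and 0.68, upward, in number-first libraries). Nuclear oxidative phosphorylation genes ranked lower (23 of 36 lower, adjusted p = 0.00812, adjusted p = 0.694 with an estimated correlation, 0.00228 with the style covariate and 0.000294 in number-first libraries). Uqcrh (-0.93, adjusted p = 0.0246) and Ndufb8 (-0.74, adjusted p = 0.0475) passed over all genes, against 3 up and 9 down over the list alone. Ribosomal protein genes ranked higher (55 of 81, adjusted p = 0.00445, adjusted p = 0.826 with an estimated correlation) but lower with the style covariate (6.01e-17) and in number-first libraries (2.98e-15), while Rps3 (-1.28), Rplp0 (-1.13) and Rpl4 (-1.34) each passed downward.

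The other large interaction values were upward for Lypla2 (5.82), Sf3a2 (5.45), Med25 (4.94), Tbl1x (4.91), Noxa1 (4.83, adjusted p = 0.00837), Phactr2 (4.81), Rpph1 (4.78) and Anxa11 (4.73). They were downward for Lars2 (-4.79) and Prkce (-3.19) and, uncertain for near-identical copies, for Mir682 (-6.81), Rn45s (-5.12), Stxbp3b (-4.80), Uchl4 (-4.23), Hist1h4i (-4.15) and Acot10 (-3.66). The limma count was 215 (157 up, 58 down) and 229 after quantile normalization (142 up, 87 down). It was 0 with the style covariate (738 at unadjusted p under 0.05) and 0 in number-first libraries (776). The median gene moved by 0.251. The count was 102, 5, 51, 122 and 637 without control replicates 1 to 5, and 133, 142 and 129 without double-mutant replicates 5, 6 and 7. It was 592, 127, 591, 128, 122 and 133 without JAK2V617F replicates 1, 2, 3, 5, 6 and 7, and it was 130, 482, 485 and 124 without Ezh2 loss replicates 1, 3, 4 and 7.

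**Figure D3:**
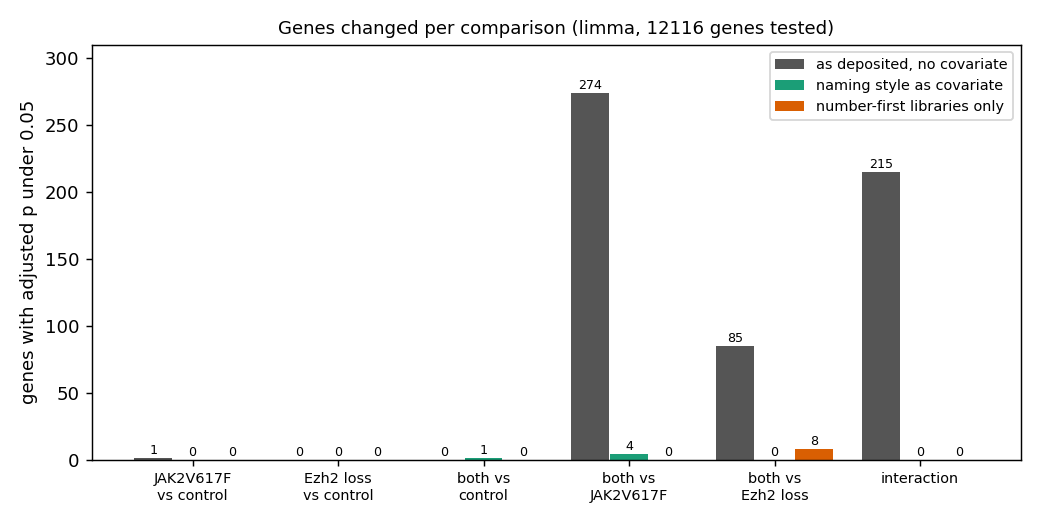
Genes passing per contrast without the style term, with it as a covariate and in number-first libraries alone. The double mutant against JAK2V617F goes from 274 to 4 to 0.

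The average effect of Ezh2 loss over both JAK2 states, from the additive fit chosen after the data were seen, raised 3 genes and lowered 4. Vwf fell (-1.43, SE 0.28, adjusted p = 0.0349). It was at 12.0 ± 7.81 and 14.4 ± 5.71 RPKM in control and JAK2V617F but 4.42 ± 1.92 and 3.77 ± 1.38 in Ezh2 loss and double-mutant HSCs. Esr1 (-2.48, SE 0.43, adjusted p = 0.0158), the growth arrest transcript Gas5 (-0.85, SE 0.16, adjusted p = 0.034) and Cyb5 (-0.35, SE 0.07, adjusted p = 0.0349) fell. Upward went Pde2a (1.98, SE 0.32, adjusted p = 0.0115), Arhgdib (0.61, SE 0.12, adjusted p = 0.034) and the uncertain Dynlt1b (2.24, SE 0.43, adjusted p = 0.034). Pde2a was at 9.13 in control and 10.2 in Ezh2 loss, against 0.814 in JAK2V617F and 22.6 in the double mutant. Dynlt1b was at 13.3 and 12.5, against 0.0631 and 22.5, so the average rise of these genes rests on the double mutant against JAK2V617F, not on Ezh2 loss against control. Esr1 was at 6.71 ± 9.25 and 2.14 ± 2.49, against 21.2 and 0.265. Its control mean holds the 23.0 of control replicate 3, and its interaction was -3.15 (adjusted p = 0.0246, and 0.694 with the style covariate). The average fall of Esr1 thus rests mostly on the double mutant against JAK2V617F. Arhgdib was at 1357 and 1929, against 1194 and 1757. Gas5 was at 450 and 321, against 740 and 307, and Cyb5 at 1012 and 862, against 967 and 648. Both were lower with Ezh2 loss in each pair, and by more between JAK2V617F and the double mutant. By naming style the mean of Vwf was 3.65 (number-first, n = 2) and 4.72 (number-last, n = 5) in Ezh2 loss, against 13.7 (n = 4) and 5.62 (n = 1) in control and 14.8 (n = 2) and 14.2 (n = 5) in JAK2V617F. The single contrasts of Vwf were -1.18 for Ezh2 loss against control, -1.35 for the double mutant against control, -1.66 for the double mutant against JAK2V617F (adjusted p = 0.02) and 0.31 for JAK2V617F against control.

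**Figure D4:**
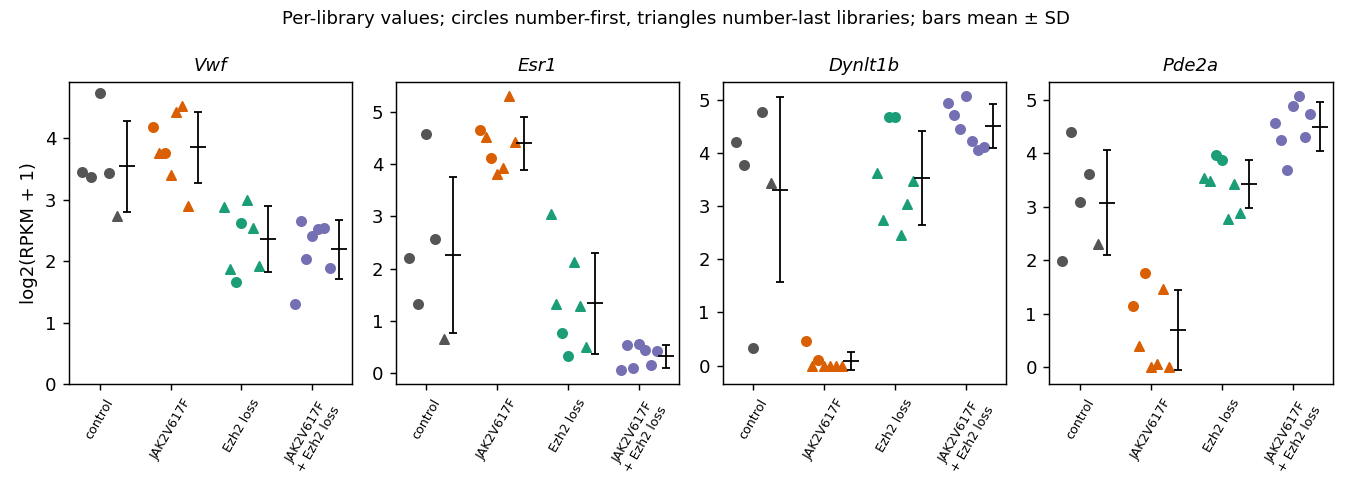
Vwf, Esr1, Dynlt1b and Pde2a per library as log2(RPKM + 1) in the 4 groups, circles for number-first and triangles for number-last libraries, bars for mean ± SD. Vwf is low in both groups with Ezh2 loss in their label.

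The count of 7 for the average effect of Ezh2 loss (1023 at unadjusted p under 0.05) was 4, 1 and 4 without control replicates 1, 3 and 4, and 11, 2 and 3 without double-mutant replicates 1, 4 and 7. It was 1, 12, 2 and 3 without JAK2V617F replicates 1, 3, 5 and 7, and 13 without Ezh2 loss replicate 3 or 6. Of 26 such settings Pde2a passed in 26, Esr1 in 24, Dynlt1b in 18, Gas5 in 17, Arhgdib in 17, Vwf in 15 and Cyb5 in 12. Without control replicate 3 only Pde2a passed (adjusted p = 0.0309), and Vwf was at -1.29 (adjusted p = 0.124). In number-first libraries alone 0 genes passed. With the neutrophil covariate Esr1, Pde2a and Bola2 passed, and without the style term Esr1 alone. Vwf, Gas5, Cyb5, Arhgdib and Dynlt1b passed in neither of these 2 fits. The average effect of JAK2V617F gave 0 genes in limma (662 at unadjusted p under 0.05, smallest adjusted p = 0.655).

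By list, the average effect of Ezh2 loss was upward for type I interferon genes (25 of 28, 10 over the list alone, adjusted p = 1.08e-09, adjusted p = 0.0824 with an estimated correlation), and granulocyte and monocyte genes (19 of 22, 3 over the list alone, adjusted p = 1.09e-06, adjusted p = 0.343 with an estimated correlation). Lymphoid priming genes were higher too (9 of 9, 4 over the list alone, adjusted p = 7.57e-05, adjusted p = 0.00865 with an estimated correlation). The average effect of JAK2V617F was downward for immediate early and stress genes (22 of 24 lower, adjusted p = 3.06e-06, adjusted p = 0.511 with an estimated correlation) and upward for MHC class II genes (9 of 9, adjusted p = 0.000285, adjusted p = 0.311 with an estimated correlation).

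Across all contrasts 44 of 144 list tests passed, 23 of them in the same direction with the style covariate, 1 with an estimated correlation and 7 with fry. PRC2 subunits, Polycomb-silenced developmental genes (5 of 30 tested), TGF-beta and BMP targets, endothelium and stroma (5 of 15), the fetal HSC programme (7 of 13), megakaryocyte and platelet genes, p53 targets, profibrotic genes (10 of 18), and the unfolded protein response passed in no contrast (smallest adjusted p = 0.176). Members under the expression filter were not tested, which leaves out most Polycomb-silenced genes. All 30 of these had values, and those left out reached RPKM of 1 in fewer than 5 libraries. A rise to that level in most libraries labelled with Ezh2 loss was thus not seen for them, while smaller rises were not examined. Cdkn2a, a known Polycomb target checked after its values were seen, was at 0 in every library, and the fetal gene Hmga2 was level at 7.19, 7.53, 7.86 and 5.69 RPKM in control, JAK2V617F, Ezh2 loss and double-mutant HSCs.

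The effects of Ezh2 loss with and without JAK2V617F, over the fold changes of 12116 genes, had Pearson r = -0.21 (Spearman -0.24, 40.6% with the same sign). Those of JAK2V617F with and without Ezh2 loss had r = -0.37 (Spearman -0.33, 36.9%). The paired contrasts share no library, but simulated data without any genotype effect and with the naming style of these libraries gave r = -0.46 (SD 0.07) and -0.45 (SD 0.07), so uneven styles alone give negative values. With the style covariate r was -0.11 and -0.25, where the same simulation gave -0.25 (SD 0.1) and -0.24 (SD 0.09). Without the covariate the jackknife SE over libraries was 0.158 for the Ezh2 effects and 0.141 for the JAK2V617F effects, so neither likeness nor difference of the effects is read from these values.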

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

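The exchanges of labels between groups were planned, while the tests within naming style and those on pseudogene copies, depth, neutrophil transcripts and Dynlt1b were chosen only after the results were seen. A library far from the rest of its group was marked in 38 of 366 groups of 93 genes, where chance marks about 1 in 20 groups, or 18.3. Of 16 libraries, control replicate 5 held 11 of the marks and JAK2V617F replicate 3 held 6.

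Control replicate 5 is the only number-last control, and its marked genes are those of the naming style. It was above the other controls in Acot10 (7.32 against 0.302 to 0.583), Cyb5 (1430 against 834 to 967), Mir682 (745 against 20.4 to 36.7), Rpl4 (2100 against 819 to 1050), Stxbp3b (5.14) and Uchl4 (61.5 against 1.68 to 3.08). It was below them in Gapdh (23.1 against 187 to 324), Gm4759 (0 against 13.1 to 21.7), Lypla2 (11.9), Sf3a2 (0.834 against 33.1 to 60.2) and Tcf15 (17.5 against 73.6 to 85.7).

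JAK2V617F replicate 3 held neutrophil transcripts that its group lacked: S100a8 (8520 against 38.8 to 85.7), Ngp (2530 against 0 to 12.2), Camp (2100), Lcn2 (339 against 0) and Retnlg (7.94 against 0). Its Rn45s was low (364 against 3270 to 6220). In the same group, Dynlt1b was at 0.369 and Arhgdib at 616 (others 1110 to 1450) in replicate 1, Fam57a at 0 in replicate 2 and Jak2 at 0.996 (others 11.4 to 18.9) in replicate 5.

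In Ezh2 loss, replicate 5 was apart in Cap1 (0.0534 against 13.7 to 61.1), Prrg4 (0.18) and S100a9 (79.9 against 1030 to 5170), replicate 4 in Clec9a (3.25) and Noxa1 (5.55 against 0), replicate 1 in Eng (15.2 against 42.9 to 58.9) and Rps27l (1310), and replicate 6 in Cd38 (5.46). In the double mutant, replicate 6 was apart in Clec9a (0.728), Irf7 (19.9 against 56.3 to 102) and Tnfrsf14 (6.71), replicate 4 in Snord47 (33.8 against 122 to 257) and replicate 1 in Tapbp (104 against 168 to 202). In control, replicate 3 was low in Beta-s (2.16), replicate 2 was high in Oasl2 (80.7 against 29.2 to 37.8), replicate 4 in Camp (39.9 against 0 to 0.299) and replicate 1 in Ddx3y (34.2 against 0 to 0.0114), a gene of the Y chromosome.

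The effect of Ezh2 loss differed between JAK2 states for 215 genes (the interaction). The real grouping alone reached this count among 100 splits (1 of 100, highest other 3). Those splits do not keep the overlap of genotype and naming style, so they cannot exclude chance. Among splits within naming style, which keep it, 41 of 100 gave as many genes (highest 707). The count can therefore be told neither from chance nor from naming style.

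For the double mutant against JAK2V617F, 274 genes passed, which only the real grouping reached among 100 splits (1 of 100, highest other 1). Within naming style 3 of 36 splits gave as many (highest 468), so chance is not excluded there. For the double mutant against Ezh2 loss, 85 genes passed, which only the real grouping reached among 100 splits (1 of 100, highest other 4). Within naming style only the real grouping of 36 reached it (1 of 36, highest other 76). Those splits cannot part style from genotype, because all double-mutant libraries are number-first and the number-last Ezh2 loss libraries stay in their group. The cause is left open. In limma 0 genes passed with the style covariate (950 at unadjusted p under 0.05) and 0 with the Xist covariate (1664). Chance cannot be excluded for JAK2V617F against control, where 12 of 100 splits gave at least the 1 real gene. The highest of these, 733 genes, put 6 number-first libraries of 7 against 0 of 5, so it followed the naming style and points to a structure of the samples. For Ezh2 loss against control (highest 10, in a split of 5 number-first of 7 against 1 of 5) and the double mutant against control (highest 3) the real count is 0, which 100 of 100 splits reach by construction, so chance was not tested there. For the average effect of Ezh2 loss, 7 genes passed. Of 100 splits within naming style and JAK2 state, 2 gave as many, the real one included (highest 23). Those splits leave the 5 number-last JAK2V617F libraries in place, and the additive fit was chosen after the data were seen. Chance is therefore not excluded for this count.

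The 2327 genes that differ between naming styles may reflect how reads shared with near-identical processed pseudogenes were counted. Genes with such a copy were called higher in number-first libraries in 27.3% of cases against 13.5% of genes without (odds ratio 2.4, 95% interval 2.03 to 2.83, two-sided Fisher's exact test p = 3.79e-23), and 17 of 40 measured processed pseudogenes were lower. Without ribosomal protein genes and within expression strata the Mantel-Haenszel odds ratio was 1.71 (1.43 to 2.04), yet 1351 of the higher calls lay in genes without a copy against 226 in genes with one, and read assignment itself was not tested. For single genes depth cannot be told from style, because 42.6% of the calls (991) remained with log2 depth as a further term. The styles overlapped in depth but not on the first principal component. Number-last Ezh2 loss replicate 6 (18.2 M reads) and JAK2V617F replicate 5 (16.2 M) lay at -53.7 and -69.7 on it. Number-first Ezh2 loss replicate 3 had fewer reads (14.2 M) and lay at 29.3. These values argue against depth alone as the cause of that component. No biological explanation was tested, and style overlaps with genotype.

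Neutrophil transcripts in HSC libraries labelled as Ezh2 loss or double mutant could come from neutrophil RNA or cells in the sorted samples. S100a8 exceeded the highest control in 10 of these 14 libraries and Ngp, Camp or Retnlg in 10 of these 10, but that was nearly fixed beforehand, as the highest control was 0 for Retnlg and 6.09 for Ngp. Ngp exceeded it in 5 of 7 JAK2V617F libraries, and JAK2V617F replicate 3 had high levels (S100a8 8520, Ngp 2530, Camp 2100), so neither low nor high levels were confined to these labels. They were more frequent there, as S100a8 exceeded the highest control in 7 of 7 Ezh2 loss and 3 of 7 double-mutant libraries, against 1 of 7 JAK2V617F libraries. A rise of S100a8 in the stem cells of every animal with such a label does less well, as 4 of 14 libraries lay at or under the highest control, but all 4 were double mutants, so it stays open for Ezh2 loss alone (7 of 7 above). Naming style does less well, because 0 of 5 number-last JAK2V617F libraries but 2 of 2 number-first Ezh2 loss libraries exceeded it, while neutrophil RNA, more neutrophils in the marrow of these animals and a neutrophil programme in some HSCs were not told apart.

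Dynlt1b, its neighbour Tmem181b-ps and Esr1 might mark a genetic background of the animals and not an effect of JAK2V617F. Of 19 libraries outside the JAK2V617F group tried with it, control replicate 3 gave 3 genes that part the sets and the next highest gave 1, but these 3 genes had prompted the count, so it does not support background. Control replicate 3 had Dynlt1b at 0.256, Tmem181b-ps at 0 and Esr1 at 23.0, like JAK2V617F libraries, while double-mutant libraries, read as carrying JAK2V617F, did not share this. Naming style explains it poorly, with 2 of 3 genes at adjusted p over 0.05 for style (Dynlt1b 0.00349, Tmem181b-ps 0.959, Esr1 0.106). Whether control replicate 3 is a mislabelled library, which would alter every contrast with control, was not tested, and its Pde2a of 7.53 lay above every JAK2V617F library (highest 2.38), so background, labelling and an effect of JAK2V617F that needs Ezh2 are left open.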

How the results depend on the processing

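No paired analysis was possible because replicate numbers follow deposition order and pair no libraries. The read-count test was not run because the table holds RPKM. Depth limits calls of low genes. Naming style limits the interaction and every contrast of a single mutant with the double mutant or with control. Ezh2 and Jak2 fold changes were kept only between groups that differ in that gene, decided after 6 of 6 others (largest 0.29) changed sign.

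JAK2V617F against control (1 gene) gave 0 with pseudocount 5, only the groups compared, the naming style covariate, number-first libraries only, the detected genes covariate, and naming style and neutrophil covariates together. It gave 2 with no filter, with RPKM of at least 5 and with TPM, Pde2a being added, and 6 with array weights. Ezh2 loss against control (0) gave 2 with only the groups compared, Retnlg (adjusted p = 0.0081) and Tas1r1. The double mutant against control (0) gave 1 with the style covariate (Gm2a) and 1 with the detected genes covariate (Cyb5, adjusted p = 0.0193).

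The double mutant against JAK2V617F (274) gave 156 with no filter, 543 with array weights, 4 with the style covariate, 0 in number-first libraries, 5 with the detected genes covariate and 5 with both covariates, Arhgdib joining Esr1, Dynlt1b and Pde2a in the last 2. The double mutant against Ezh2 loss (85) gave 13 with no filter, 54 with TPM, 150 with array weights, 0 with the style covariate, 8 in number-first libraries, 0 with detected genes, 0 with Xist, 45 with the neutrophil covariate and 3 with both (Gm2a, Insig1, Mtmr2). The interaction (215) gave 122 with no filter, 779 with array weights, and 0 with the style covariate, in number-first libraries, with detected genes and with both covariates. The average effect of Ezh2 loss (7) gave 1 without the style term (Esr1) and 3 with the neutrophil covariate (Esr1, Pde2a and Bola2, which was not among the 7). It gave 11 with pseudocount 0.1 and 0 in number-first libraries. Of 144 list tests, 44 passed, 1 passed with an estimated correlation, 7 with fry, 39 with pseudocount 0.1, 37 after quantile normalization, 31 with the style covariate and 31 in number-first libraries.

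Leaving out a library gave 0 to 3 genes for JAK2V617F against control, 0 to 1 for Ezh2 loss against control, 0 to 0 for the double mutant against control, 83 to 673 against JAK2V617F and 0 to 218 against Ezh2 loss. It gave 5 to 637 for the interaction, 1 to 13 for the average effect of Ezh2 loss and 0 to 0 for that of JAK2V617F. The similarity of effects ran from -0.29 to -0.158 for Ezh2 and from -0.436 to -0.305 for JAK2V617F. For these ranges the cause was not tested. Reversed were Ezh2 in Ezh2 loss against control (0.08) and Acot10 in the interaction (0.05) in number-first libraries, and in the interaction Sf3a2 (-0.373) and Uchl4 (0.178) with both covariates, and the cause was not tested. For genes that meet the naming rule, the call was the same in 2596 leave-one-out tests, lost in 771 and gained in 8. With the style covariate it was the same in 23 and lost in 100, with no change of sign. Same also covers genes named as not passing that passed in neither fit. Only 3 calls were kept with the style covariate, Esr1, Dynlt1b and Pde2a in the double mutant against JAK2V617F.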

Other observations

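The fetal gene Lin28b was at 0.445, 0.0455, 2.44 and 1.51 RPKM in control, JAK2V617F, Ezh2 loss and double-mutant HSCs, and its average fold change with Ezh2 loss did not pass (1.04, adjusted p = 0.367). Just past the threshold for the average effect of Ezh2 loss lay Fhl1 (-1.18, adjusted p = 0.0549), Cybb (2.34, adjusted p = 0.0549), Ppic (-0.65, adjusted p = 0.0549), Socs2 (-1.31, adjusted p = 0.0747) and Retnlg (3.97, adjusted p = 0.101). Cybb and Retnlg belong to mature myeloid cells, and Fhl1 is on the quiescence list. Socs2 was lowest in Ezh2 loss, at 10.7 RPKM, against 41.1, 34.9 and 24.9 in control, JAK2V617F and double-mutant HSCs.

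Further lists moved with the average effect of Ezh2 loss under the preset correlation only. Inflammation (13 of 21 higher, 2 over the list alone, adjusted p = 0.00306, adjusted p = 0.387 with an estimated correlation), erythroid (9 of 12, 2 over the list alone, 0.00179 and 0.511) and cell cycle genes (32 of 44, 0 over the list alone, 0.0268 and 0.814) were higher. MYC and ribosome biogenesis (19 of 24 lower, 1 over the list alone, 0.0143 and 0.511) and ribosomal protein genes (76 of 81 lower, 4.73e-10 and 0.667, in a fit that holds the style covariate, on which their direction depends in the single contrasts) were lower. With the average effect of JAK2V617F, erythroid genes were lower (9 of 12 lower, 0.00947, and 0.667 with an estimated correlation), as were ribosomal protein genes (73 of 81 lower, 7.22e-05 and 0.8), again with the style covariate.

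The naming style itself moved lists: JAK-STAT target genes were higher in number-first libraries (17 of 21, adjusted p = 0.00935, adjusted p = 0.0824 with an estimated correlation) and cell cycle genes lower (36 of 44 lower, 0.000334 and 0.759). Those are the directions in which both lists moved in the interaction.

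Mature cell transcripts varied between libraries. Elane and Mpo, genes of granulocyte precursors, were at 3639 and 1622 RPKM in Ezh2 loss replicate 4 and at 418 and 230 in double-mutant replicate 7. Beta-s was at 877, 3394, 1607 and 5786 in Ezh2 loss replicates 1, 2, 5 and 6. Retnlg was at 81.6, 526 and 6.78 in double-mutant replicates 3, 4 and 7 and from 12.7 to 449 in the Ezh2 loss libraries. Vwf ran from 2.15 to 6.96 in Ezh2 loss and from 1.47 to 5.26 in the double mutant, against 6.47 to 22.1 in JAK2V617F and 5.62 to 25.7 in control, where the highest value was that of control replicate 3.

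Both Xist and Ddx3y, of the inactive X and the Y chromosome, were present in Ezh2 loss replicate 3 (0.744 and 10.9) and double-mutant replicate 3 (7.74 and 6.39), and the sex of the animals is not given in the sources used here.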
